A study of Danio rerio with 12 samples.

How the data were processed

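The data were expression values of 12 Affymetrix zebrafish arrays hybridised with total RNA from whole embryos of 4 genotypes, 3 arrays each, at 80 hours post fertilization. Genotypes were taken from the sample labels and replicate numbers from the sample titles. Values had been made with GCRMA, per the submitters' processing notes, which give no version.

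The deposited values were on the log2 scale, and the file did not state further steps. Their scale was worked out from the values: taken as powers of 2, 13937 of 15617 probe sets (89.2%) had a linear median over the 12 arrays of 1 within a tolerance of 0.0001, against 9844 as powers of e and 4286 as powers of 10. In the other 1680 probe sets the median lay below 1 and in 0 above it. Each probe set was thus centred near its own median, and how bright it was stays unknown, as does the divisor of those 1680. A value of 0 means the median of the 12 arrays and not absence. Signal over background could not be read from the table, so a change in a dim probe set cannot be told from a change in a bright one. Median log2 values per array ran from -0.036 to 0.081, and the widest array was BRAF replicate 1 with an SD of 0.532.

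A filter at 4 on the log2 scale on at least 3 arrays had been planned, with 6 as the stricter alternative, together with a pseudocount alternative. None could be applied to centred values, so the filter was left out and all 15502 probe sets other than the 115 Affymetrix controls were tested. None of these controls passed in any contrast when they were fitted with the rest.

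Probe sets were named from the platform annotation, with symbols checked through Entrez identifiers: 10795 had 1 symbol, 135 several and 4572 none, and 10711 of the former were found in the RefSeq gene table. There were 8793 distinct symbols. Probe sets with several symbols were not named, and no genome coordinates were used.

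Differences were tested in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, fitting 1 mean per genotype over all 12 arrays and no block. The 5 pairwise contrasts and the interaction were each adjusted by Benjamini-Hochberg over the 15502 probe sets at a threshold of 0.05. All tests were two-sided unless stated. The 22 gene lists were tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, on 1 probe set per gene. That was the probe set with the highest mean over the 12 arrays, which in centred data is not the brightest. Lists with at least 5 measured genes were tested, and p-values were adjusted over the 22 lists. The lists were neural crest progenitors, melanophores, xanthophores, iridophores, purine and pyrimidine synthesis, p53 targets, ERK pathway output, cell cycle, myelin, neurons, radial glia, photoreceptors, lens crystallins, skeletal muscle, liver, exocrine pancreas, intestine, erythrocytes, leukocytes, cartilage and bone, heat shock and stress, and circadian and glucocorticoid genes. The camera direction differed in sign from the list's mean or median difference in 22 of 132 list results, of which 0 passed.

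Groups, tests, lists and the rule for naming genes were fixed before the data were examined. For each comparison with wild type the rule took, among probe sets with 1 symbol, a passing adjusted p and no overlap between the arrays of the groups, the 10 genes with the largest rise and the 10 with the largest fall. For the remaining contrasts it took 5 and 5, by smallest p and without the overlap condition in the interaction. It added up to 4 members of each list by smallest p, of which those past the threshold and a few others are reported, and 13 genes named in advance. In the 132 named pairwise calls the arrays of the groups did not overlap in 132.

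The fit was tested on simulated data for BRAF;p53 against wild type over 15502 probe sets, with 50 changed probe sets per fold size. It recovered 30% of changes of 0.5 on the log2 scale, 70% of 1, 90% of 2 and 96% of 3, with 8 false calls among 151. The simulated errors were independent and normal, with the same SD in every genotype. These figures therefore do not show how the fit performs where spread differs between genotypes or samples are related. The sharing of wild-type arrays was examined with 100 simulations of unchanged groups. Alternatives were quantile normalization, centred array medians, eBayes with trend and robust settings, a replicate block, averaging p53 samples 1a and 1b, 1 probe set per gene, an absolute log2 change of at least 1, only the genotypes compared, and each array left out in turn. Those added after seeing the data left out probe sets with a median below 1, averaged the probe sets of each gene, or left out the 2 arrays farthest from their genotype. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.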

Results

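Gene expression was measured in whole zebrafish embryos at 80 hours post fertilization with an Affymetrix oligonucleotide array of 15617 probe sets. The 12 arrays covered 4 genotypes with 3 arrays each: wild type of the Tu strain, embryos homozygous for a transgene expressing activated BRAF from the mitf promoter (BRAF), p53 mutants (p53), and embryos with both (BRAF;p53). The mitf promoter is active in pigment cells and their precursors, and BRAF feeds the ERK signalling cascade. The comparisons asked what the transgene changes with and without p53 function. The labels do not say how many embryos or clutches went into each RNA sample, and 2 of the p53 samples carry the names 1a and 1b. The p-values therefore measure only the spread between these samples, which may be partly technical. No depth applies to arrays, and their number limits the precision.

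Components 1 and 2 held 30.4% and 19.8% of the variance and set apart BRAF and wild-type arrays, but not p53 from BRAF;p53 arrays. BRAF arrays scored 22.5 to 47.3 on component 1, above all other arrays, while wild-type arrays scored 17.8 to 25.6 on component 2, where BRAF arrays spanned -26.1 to 17.1. On component 3, with 15.9% of the variance, p53 arrays scored 6.3 to 27.6 and BRAF;p53 arrays -23.7 to -12.9. BRAF replicate 1 and p53 replicate 3 lay apart from their own genotypes. The correlation across probe sets of BRAF replicate 1 with the other BRAF replicates was 0.56 and 0.41, against 0.83 between those replicates. For p53 replicate 3 it was 0.47 and 0.48, against 0.75 between the other p53 replicates. Those are samples 1a and 1b, which may share a source, so replicate 3 need not be the deviating array. The 3 BRAF;p53 arrays correlated at 0.76 to 0.84. Probe sets are not independent replicates.

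**Figure D1:**
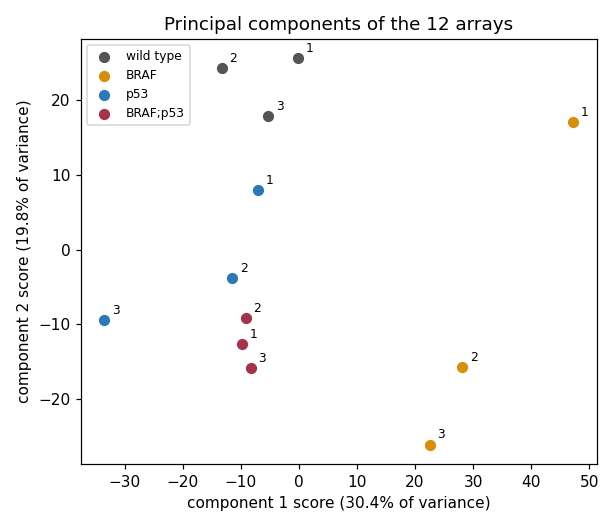
Scores of the 12 arrays on principal components 1 (horizontal) and 2 (vertical), in component units, coloured by genotype and numbered by replicate. BRAF arrays score 22.5 to 47.3 on component 1, and p53 replicate 3 has the lowest score, -33.5.

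In BRAF;p53 embryos, crestin, a transcript of zebrafish neural crest and its derivatives, was 1.22 ± 0.17 higher than in wild type on the log2 scale (SE, n = 3 per genotype; limma adjusted p = 0.00279). The ERK feedback inhibitor gene spry4 rose by 0.71 ± 0.09 (limma adjusted p = 0.0018). The p53 target rps27l fell by 0.97 ± 0.12 (limma adjusted p = 0.00173), and fabp1b.1, which encodes a fatty acid binding protein of the gut, fell by 1.31 ± 0.23 (limma adjusted p = 0.0123). The cartilage link protein gene hapln1a rose by 1.25 (limma adjusted p = 0.000132) and slc2a15b of the xanthophore list by 0.66 (limma adjusted p = 0.0266). The hapln1a call rested on 1 of its 6 probe sets, whose companions ranged from -0.39 to 0.08. The slc2a15b call held in 6 of 12 fits that each left out 1 array, and its adjusted p reached 0.118 without BRAF;p53 replicate 1.

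Other neural crest and pigment genes did not pass the test in BRAF;p53 embryos against wild type. The log2 difference was 0.06 for sox10, 0.15 for mitfa and 0.38 for dct (limma adjusted p = 0.973, 0.859 and 0.712). It was 0.73 for tyr, which encodes tyrosinase of melanin synthesis (limma adjusted p = 0.0787). The myelin gene mbpa had a difference of -0.48 (adjusted p = 0.355), the ERK target dusp6 of -0.18 (adjusted p = 0.578) and the pyrimidine synthesis gene dhodh of -0.14 (adjusted p = 0.77). Among p53 targets, mdm2 had -0.30 and ccng1 -0.09 (adjusted p = 0.53 and 0.842).

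The 10 largest rises against wild type were in top1a, micos13, add1, stk3, cmasa, nrarpa, ckba, cab39l1, ublcp1 and cbln11. They ran from 4.12 ± 0.37 for top1a, the DNA topoisomerase I gene, to 1.90 ± 0.20 for cbln11 (limma adjusted p = 0.000183 and 0.000472). The 10 largest falls were in slc25a14, anxa6, col1a2, zgc:112271, capn2l, dync1i2b, LOC567883, cyp2p9, sult1st1 and acsl1a. The mitochondrial carrier gene slc25a14 had -5.77 ± 0.22 (limma adjusted p = 2.46e-07), the annexin gene anxa6 -4.33 and the type I collagen gene col1a2 -4.06. Of these 20 genes, 10 had another probe set, and in 3 of the 10 another probe set moved the same way by at least 0.5 of the change. In slc25a14 and acsl1a that probe set had the same target as the named probe set. The acsl1a probe sets of another target had -0.53 and -0.35. The other top1a probe sets ranged from -0.15 to 1.08, none past the threshold (limma adjusted p = 0.06 for the highest). For nrarpa, another probe set had -1.60 against 2.64 for the named probe set. For col1a2 the other probe set had -0.28, and for slc25a14 a probe set outside the same target had 0.08. The ublcp1 call held in 7 of 12 fits without 1 array, with a limma adjusted p of up to 0.116 without BRAF;p53 replicate 1. Calls for LOC567883 and fabp1b.1 held in 10, with up to 0.0743 without BRAF;p53 replicate 3 and 0.0616 without BRAF;p53 replicate 2.

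Over all 15502 probe sets, 302 differed between BRAF;p53 and wild type at a limma adjusted p under 0.05, 151 higher and 151 lower. The groups did not overlap in 25.3% of all probe sets, where chance gives 10% for 3 arrays against 3. None of the 22 gene lists passed the camera test against the other genes, with adjusted p = 0.0747 for p53 targets. The adjusted p was 0.1 for melanophores and for cell cycle, and 0.117 for intestine. It lay between 0.258 and 0.999 for exocrine pancreas, erythrocytes, ERK pathway output, myelin, photoreceptors, iridophores, purine and pyrimidine synthesis, skeletal muscle, liver, neurons, leukocytes, stress genes, cartilage and bone, xanthophores, neural crest progenitors, radial glia, circadian genes and lens crystallins. Of the 20 measured p53 targets 18 had a negative difference, 1 fell over all probe sets and 2 fell adjusted over the list alone. Of 8 measured melanophore genes 6 were above wild type, 0 passed over all probe sets and 2 rose adjusted over the list alone. The count was 774 after quantile normalization and 836 with only these 6 arrays fitted. It ran from 162 without BRAF;p53 replicate 1 to 510 without BRAF replicate 1.

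**Figure D2:**
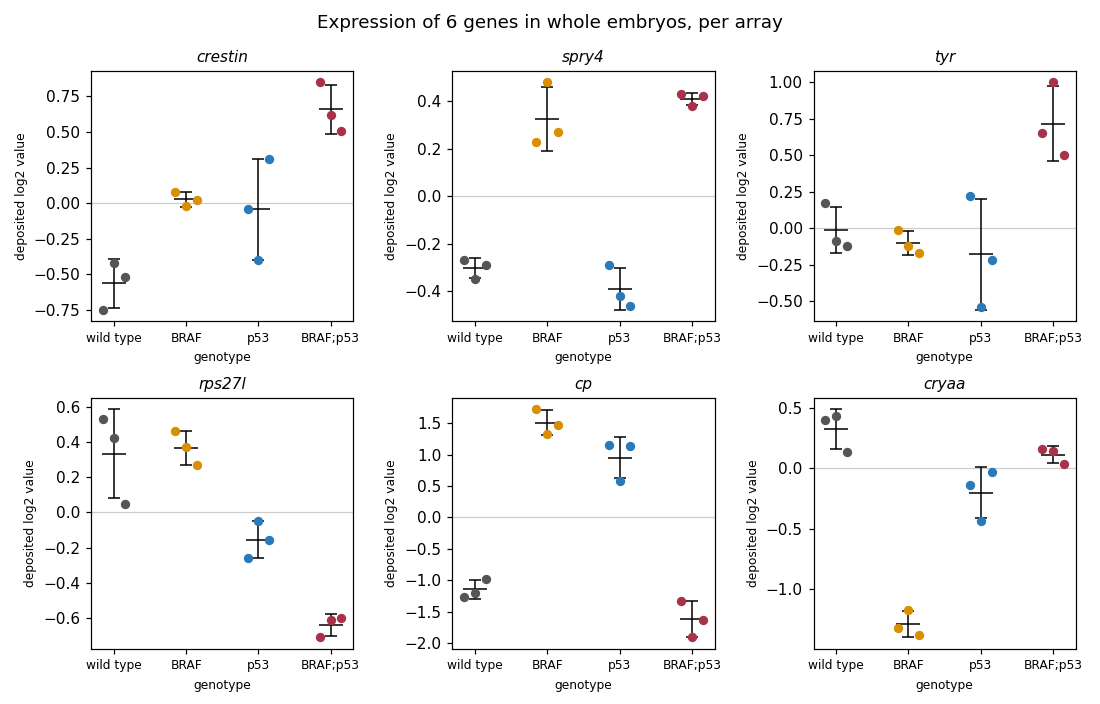
Deposited log2 value (vertical) of crestin, spry4, tyr, rps27l, cp and cryaa by genotype (horizontal). Points are single arrays and bars show the mean ± SD of 3 arrays. Mean crestin is -0.56 in wild type and 0.66 in BRAF;p53, and mean cp is 1.51 in BRAF and -1.62 in BRAF;p53.

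In embryos with the BRAF transgene alone, spry4 rose by 0.63 ± 0.09 against wild type (SE, n = 3 per genotype; limma adjusted p = 0.00181). The ceruloplasmin gene cp, whose product carries copper in plasma, rose by 2.65 ± 0.19 (limma adjusted p = 1.55e-05). The lens chaperone gene cryaa fell by 1.61 ± 0.12 (limma adjusted p = 2.82e-05), and the glucocorticoid-induced tsc22d3 rose by 0.83 ± 0.15 (limma adjusted p = 0.00679). The crestin difference of 0.59 did not pass (limma adjusted p = 0.0598), nor did 0.15 for mitfa, 0.28 for dct, -0.16 for sox10, -0.16 for mdm2 or 0.01 for ccng1.

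Of 21 measured liver genes, 3 rose and 2 fell in BRAF embryos. The fibrinogen gene fgb rose by 0.49, whereas the complement gene c9 fell by 0.64 and the vitronectin gene vtnb by 0.62 (limma adjusted p = 0.0177, 0.00415 and 0.0317). Of 18 genes of ERK output 2 rose, spry4 and spred1, the latter by 0.68 (limma adjusted p = 0.041) on 1 of 4 probe sets, with 0.08 to 0.30 on the others. Of 26 cell cycle genes, the cyclin gene ccnb1 fell by 0.65 (limma adjusted p = 0.0484). The thymidine kinase gene tk1 rose by 0.72 on its representative probe set (limma adjusted p = 0.0077), and its other probe set had -0.80. The neural crest and iridophore gene pax7a fell by 1.32 on 1 of 4 probe sets. The purine synthesis gene paics fell by 0.71, the glutamine synthetase gene glula by 0.53, the photoreceptor-list gene gnb1b by 0.66, the cartilage matrix gene matn1 by 0.55 and the heat shock factor gene hsf2 by 0.73. The muscle filament gene desma rose by 0.62. Of these, ccnb1 held in 1 of 12 fits without 1 array, glula in 2, pax7a and spred1 in 3, desma in 4, and paics, vtnb and matn1 in 6. The highest adjusted p among those fits was 0.168, for ccnb1 without wild_type replicate 2.

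The largest rises in BRAF embryos were in wls, si:dkeyp-73d8.9, top1a, mchr1b, add1, ckba, tmem263, cbln11, abat and pm20d1.1. The Wnt secretion gene wls had 7.13 ± 0.93 (limma adjusted p = 0.00112), with -0.25 and 0.16 on its other probe sets. The largest falls were in ube2q2, slc25a14, rnf13, anxa6, col1a2, si:dkey-238c7.12, copb2, tmem254, psmb10 and sarm1, led by -6.19 ± 0.33 for the ubiquitin conjugation gene ube2q2 (limma adjusted p = 1.82e-06). In 1 of the 9 genes with another probe set did one move the same way by at least 0.5 of the change. That gene was slc25a14, through a probe set of the same target, and its probe set of another target had 0.30.

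BRAF embryos differed from wild type in 993 of 15502 probe sets, 494 higher and 499 lower (limma). The exocrine pancreas list was higher against the other genes (camera adjusted p = 0.0397), with adjusted p = 0.823 with an estimated correlation. All 17 measured pancreas genes had a positive difference and 0 passed by themselves, among them the elastase gene ela3l at 3.42 ± 1.29 and the carboxypeptidase gene cpa4 at 1.69 ± 0.59 (limma adjusted p = 0.159 and 0.128). Without wild_type replicate 2 the pancreas call ended, at adjusted p = 0.671, and it held in 7 of 12 such fits. With a replicate block, or without probe sets of median below 1, 0 lists passed camera in this comparison. The lens list passed fry, which asks whether its genes move 1 way (adjusted p = 0.000809), but not camera (adjusted p = 0.455), and cryaa was the only 1 of its 6 measured genes to pass alone. The probe set count ran from 595 without wild_type replicate 2 to 1188 without BRAF replicate 1, and was 598 with only these 6 arrays fitted.

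In p53 mutants, cp rose by 2.1 ± 0.19 against wild type (SE, n = 3 per genotype; limma adjusted p = 0.000157), and paics rose by 1.07 ± 0.18 (limma adjusted p = 0.0144). The gene vtnb fell by 0.84 ± 0.15 (limma adjusted p = 0.0158), and the cartilage gene cnmd fell by 0.92 ± 0.19 (limma adjusted p = 0.0359). The p53 targets did not pass: rps27l had -0.49, ccng1 -0.27 and mdm2 0.08 (limma adjusted p = 0.0756, 0.227 and 0.887). The crestin difference was 0.52 (adjusted p = 0.163), spry4 had -0.09 and dhodh -0.41 (adjusted p = 0.731 and 0.143). The cnmd call held in 4 of 12 fits without 1 array, with an adjusted p of up to 0.119 without wild_type replicate 3, vtnb in 9 (0.0667 without wild_type replicate 1) and paics in 11 (0.0568 without wild_type replicate 3).

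The largest rises in p53 mutants were in top1a, cmasa, mchr1b, si:ch1073-340i21.3, ckba, igldcp, pbldp, st6gal2a, si:dkey-22l11.6 and zgc:113162. The largest falls were in slc25a14, anxa6, zgc:112271, tln2a, thy1, bphl, psmb10, zbtb16a, rtkn2 and LOC567883. The extremes were 5.06 ± 0.37 for top1a and -5.54 ± 0.22 for slc25a14 (limma adjusted p = 4.15e-05 and 7.74e-07). The other top1a probe sets ranged from -0.045 to 1.832 (limma adjusted p = 0.00452 for the highest). Another probe set moved the same way by at least 0.5 of the change in 1 of the 6 genes that had one. That gene was slc25a14, through a probe set of the same target, and its probe set of another target had -0.20. Of these 20 genes 6 lost their call in some fit without 1 array, the least stable being igldcp, which held in 3 of 12 (adjusted p of up to 0.133 without wild_type replicate 1), and tln2a and LOC567883, which held in 7. Between p53 mutants and wild type 284 of 15502 probe sets differed, 117 higher and 167 lower, and no gene list passed camera. The lowest adjusted p was 0.0622, for the liver list, in which 14 of 21 measured genes had a positive difference. The count was 156 with samples 1a and 1b averaged and 105 with only these 6 arrays fitted, and ran from 161 without wild_type replicate 1 or 2 to 466 without BRAF replicate 1.

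Against p53 mutants, BRAF;p53 embryos had more spry4, by 0.80 ± 0.09 (SE, n = 3 per genotype; limma adjusted p = 0.000771), and more tyr, by 0.90 ± 0.19 (limma adjusted p = 0.0267). They also had more hapln1a, by 1.13, and more slc2a15b, by 0.83 (limma adjusted p = 0.000292 and 0.00642). The crestin difference of 0.70 ± 0.17 passed (limma adjusted p = 0.0479) in the fit of all arrays and in 2 of 12 fits without 1 array, with an adjusted p of 0.2 without BRAF;p53 replicate 1. The tyr call held in 9 such fits (adjusted p of up to 0.117 without BRAF;p53 replicate 2). Lower in BRAF;p53 were cp, by -2.58 ± 0.19, fabp1b.1, by -1.67 ± 0.23, paics, by -1.41 ± 0.18, and the p53 target pmaip1, by -1.77 ± 0.37 (limma adjusted p = 4.67e-05, 0.00262, 0.00204 and 0.029). The pmaip1 probe set had a companion at -0.09, and its call held in 7 of 12 fits.

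The largest rises of BRAF;p53 over p53 were in micos13, stk3, shmt2, tln2a and ptpra, from 3.21 to 2.34. The largest falls were in col1a2, si:ch1073-340i21.3, cp, cnpy3 and igldcp, from -4.03 to -2.51, and in 0 of the 2 genes with another probe set did one move as far as 0.5 of the change. The tln2a call held in 2 of 12 fits without 1 array (adjusted p of up to 0.162 without BRAF;p53 replicate 2), igldcp in 6 and si:ch1073-340i21.3 in 8. Probe sets that differed numbered 456, 233 higher and 223 lower in BRAF;p53. The exocrine pancreas list was lower (camera adjusted p = 0.00359, and adjusted p = 0.983 with an estimated correlation), as was the intestine list (adjusted p = 0.00746, and 0.942 as the adjusted p with an estimated correlation). Of 17 measured pancreas genes 16 had a negative difference and 0 passed, and of 17 intestine genes fabp1b.1 fell. Both list calls ended without p53 replicate 2, at adjusted p = 0.237 for pancreas and 0.135 for intestine. The melanophore list had adjusted p = 0.0514, with 6 of 8 genes higher, 1 past the threshold and 2 adjusted over the list alone. The count was 697 after quantile normalization and 254 with samples 1a and 1b averaged, and ran from 179 without BRAF;p53 replicate 1 to 688 without BRAF replicate 1.

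Against BRAF embryos, BRAF;p53 embryos had less of the p53 targets rps27l, by -1.0 ± 0.12, and plk3, by -0.73 ± 0.10 (SE, n = 3 per genotype; limma adjusted p = 0.00119 and 0.00294). The ERK inhibitor gene spred1 was lower by -0.89 ± 0.17 (limma adjusted p = 0.0162) on 1 of 4 probe sets, with -0.48 to -0.10 on the others, none past the threshold, and spry4 differed by 0.08 (adjusted p = 0.615). Of the pigment lists, 1 of 8 melanophore, 1 of 8 xanthophore and 1 of 5 iridophore genes were higher, with 0.82 ± 0.19 for tyr, 1.19 ± 0.21 for the pteridine synthesis gene gch2 and 0.65 ± 0.12 for slc2a11b of the iridophore list (limma adjusted p = 0.0311, 0.00947 and 0.0106). The carotenoid cleavage gene bco1 of the xanthophore list was lower, by -1.46 (limma adjusted p = 0.0113), and no pigment list passed camera (adjusted p = 0.295 for melanophores, 0.452 for xanthophores and 0.0899 for iridophores). The tyr call held in 7 of 12 fits without 1 array, with an adjusted p of up to 0.136 without BRAF;p53 replicate 2.

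Among other lists, cp was lower in BRAF;p53 than in BRAF by -3.13 ± 0.19 and c9 higher by 0.69 (limma adjusted p = 8.03e-06 and 0.00457). The gene cryaa was higher by 1.40 ± 0.12 and hapln1a by 0.91 ± 0.11 (limma adjusted p = 0.000172 and 0.00103). Stress genes went both ways, with -0.63 for xbp1 of the unfolded protein response, -0.63 for the glutathione synthesis gene gclc and 0.82 for the small heat shock gene hspb8. The gene tk1 had -0.90 on its representative probe set and 0.90 on the other. The photoreceptor list held gnb1b at 0.64 and prph2a at -0.57, and the bone regulator runx2b had -0.75. Calls for prph2a and runx2b held in 5 of 12 fits without 1 array, those for gnb1b and wls in 8, and those for bco1, spred1, gclc and hspb8 in 10. The largest rises were in ube2q2 (7.0), copb2, mhc1zba, acvr2ba and lgals3b, and the largest falls in wls (-4.06), si:dkeyp-73d8.9, sppl2, cp and rorcb. Of these 10 genes 3 had another probe set, and in 0 of the 3 did one move the same way by at least 0.5 of the change.

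BRAF;p53 and BRAF embryos differed in 698 probe sets, 314 higher and 384 lower in BRAF;p53. Camera called 4 lists: exocrine pancreas lower (adjusted p = 0.000127), p53 targets lower (0.0392), intestine lower (0.0392) and erythrocytes higher (0.0285). For each of the 4 the adjusted p was 0.679 with an estimated correlation. Of 20 measured p53 targets 17 had a negative difference and 2 fell. All 17 pancreas genes had a negative difference, 0 fell over all probe sets and 6 fell adjusted over the list alone. Of 17 intestine genes 14 were lower and 0 passed, and of 15 erythrocyte genes 11 were higher and 0 passed. The p53 target, intestine and erythrocyte calls held in 9, 8 and 9 of 12 fits without 1 array, and the pancreas call in all 12. The highest camera adjusted p was 0.152 for p53 targets and 0.0948 for erythrocytes, both without BRAF replicate 3. For intestine it was 0.248, without BRAF replicate 2. The lens list passed fry (adjusted p = 0.00178) with cryaa as its only member past the threshold, as did the p53 targets (0.0466). The probe set count ran from 302 without BRAF;p53 replicate 1 to 982 without p53 replicate 3.

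The interaction asked whether the transgene changed expression by a different amount with and without p53 function. Expression of cp was higher in BRAF embryos and in p53 mutants than in wild type. In BRAF;p53 its mean was -1.62 ± 0.29 against -1.15 ± 0.14 in wild type (SD, n = 3), and the interaction was -5.23 ± 0.26 (SE, limma adjusted p = 8.02e-06). The mean of cryaa was -1.29 ± 0.11 in BRAF and 0.11 ± 0.07 in BRAF;p53 (SD, n = 3), with an interaction of 1.92 (limma adjusted p = 0.000218). The interaction was -0.68 for plk3, 0.79 for hapln1a, 0.99 for vtnb and 1.14 for cnmd (limma adjusted p = 0.0304, 0.0175, 0.029 and 0.047). It did not pass for crestin at 0.11, spry4 at 0.17, sox10 at 0.57, rps27l at -0.51 or tyr at 0.99 (limma adjusted p = 0.822, 0.5, 0.214, 0.14 and 0.0702). Among the named list members cnmd and gnb1b held in 2 of 12 fits without 1 array, vtnb in 3 and plk3 in 5.

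An interaction passed in 497 of 15502 probe sets, 249 positive and 248 negative. The smallest p-values were for slc25a14 (5.12), ube2q2 (7.32), sult1st1 (2.29), zbtb16a (3.02) and znhit1 (2.36) on the positive side, and cp, pbldp (-2.81), mchr1b (-4.89), st6gal2a (-2.91) and sult6b1 (-2.11) on the negative side. In 5 of these 10, slc25a14, sult1st1, pbldp, mchr1b and st6gal2a, all 3 mutant genotypes had changed the same way against wild type. For slc25a14 the mean was 5.48 in wild type, 0.12 in BRAF, -0.06 in p53 and -0.29 in BRAF;p53. For mchr1b BRAF;p53 also differed from p53, by -1.08 (limma adjusted p = 0.0479), where BRAF differed from wild type by 3.81, and for st6gal2a these were -1.05 (adjusted p = 0.00572) and 1.86. The other probe set of mchr1b had an interaction of -0.07. The exocrine pancreas list had a negative interaction (camera adjusted p = 4.8e-05) and so had the intestine list (adjusted p = 0.0295), with an adjusted p of 0.741 for both with an estimated correlation. All 17 pancreas genes and 15 of 17 intestine genes had a negative interaction, and 0 of either passed over all probe sets. By fry the lens and liver lists passed (adjusted p = 0.00159 and 0.0389), but not by camera (adjusted p = 0.189 and 0.296). The liver list, which holds cp, had a mean interaction of -0.42 and a median of -0.18. The intestine call held in 7 of 12 fits without 1 array, with adjusted p = 0.154 without BRAF replicate 2. The probe set count was 312 with samples 1a and 1b averaged and ran from 284 without BRAF;p53 replicate 1 to 787 without p53 replicate 3.

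**Figure D3:**
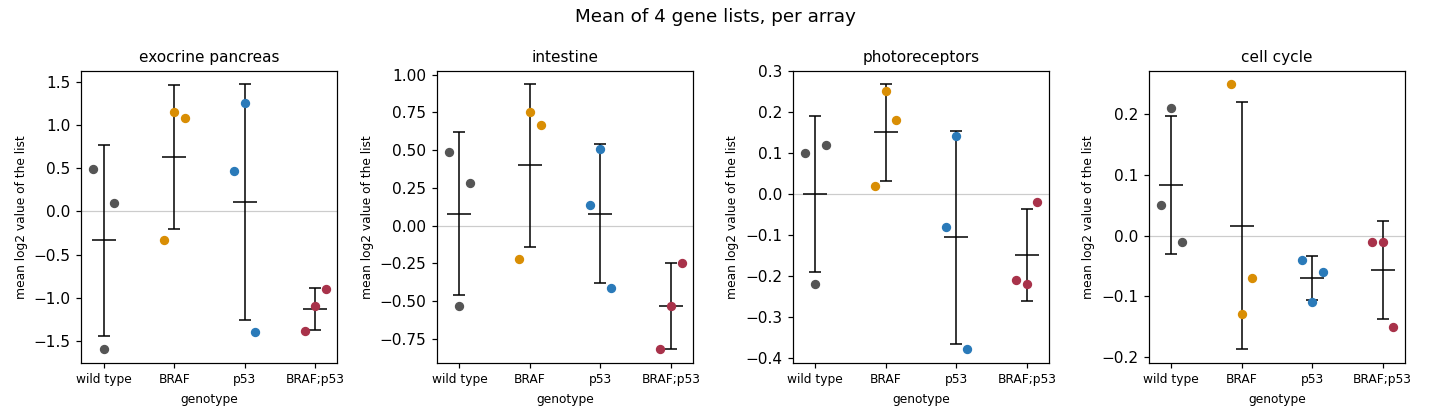
Mean deposited log2 value over the measured genes of the exocrine pancreas, intestine, photoreceptor and cell cycle lists (vertical) by genotype (horizontal). Points are single arrays and bars show the mean ± SD of 3 arrays. The pancreas mean spans -1.60 to 0.49 within wild type and -1.40 to 1.26 within p53 mutants.

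Pancreas genes varied widely within genotypes, by up to 2.65 of a range of 2.86 over all arrays. The mean of the exocrine pancreas list was 0.49, -1.60 and 0.10 on the wild-type arrays, -0.33, 1.15 and 1.08 on the BRAF arrays, 0.47, 1.26 and -1.40 on the p53 arrays, and -1.39, -1.10 and -0.90 on the BRAF;p53 arrays. An exact permutation test over 15400 groupings of the 12 arrays into 4 sets gave p = 0.269 for the spread of the genotype means (larger spread, 1-sided; Benjamini-Hochberg p = 0.456 over 22 lists).

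The transgene's effects with and without p53 function, measured on different arrays, correlated weakly across probe sets (r = 0.15, jackknife SE 0.109 over arrays; rho = -0.007). Of 157 probe sets changed in both comparisons, where independent lists give 29.2, 111 went the same way and 46 opposite ways. The effects of p53 loss with and without the transgene had r = 0.084 (jackknife SE 0.251), and of 60 probe sets changed in both 23 went the same way and 37 opposite ways.

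The 3 comparisons against wild type share the wild-type arrays. BRAF;p53 and BRAF shared 100 probe sets higher and 94 lower than wild type, where independent lists give 4.8 and 4.9 and simulated unchanged groups, which hold almost no calls, gave 0. BRAF;p53 and p53 shared 31 higher and 48 lower, against 1.1 and 1.6 for independent lists. BRAF and p53 shared 58 higher and 71 lower, against 3.7 and 5.4. The covariance of fold changes was 0.0658, 0.0558 and 0.045 for these pairs, against simulated values of 0.0201, 0.02 and 0.02. The correlation was 0.46, 0.5 and 0.33, no higher than the 0.5 simulated for each pair. Since 3 wild-type arrays cannot be split into sets of at least 2 each, part of the excess may come from the shared arrays. In 64 probe sets all 3 mutant genotypes differed from wild type the same way, 26 higher and 38 lower, among them top1a, ckba and slc25a14.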

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

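Of the tests in this part, the one that left out BRAF replicate 1 was chosen after the counts had been seen. The results here are those that passed the interaction test of the limma fit over 15502 probe sets, in which the BRAF and wild-type difference was not the same as the BRAF;p53 and p53 difference.

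The interaction passed in 497 probe sets. Of 100 drawn splits of the 12 arrays into 4 sets of 3, the real one included, 1 gave as many, and the highest other split gave 57. An arbitrary grouping of the arrays thus did not give this number. The drawn splits mix genotypes, whose differences then widen the residual spread. This count therefore cannot tell an interaction from other differences between genotypes. Among named probe sets, the 5 positive and 5 negative interactions with the smallest p were 7.32 for ube2q2, 5.12 for slc25a14, 3.02 for zbtb16a, 2.36 for znhit1 and 2.29 for sult1st1, and -5.23 for cp, -4.89 for mchr1b, -2.91 for st6gal2a, -2.81 for pbldp and -2.11 for sult6b1. In 5 of these 10, slc25a14, sult1st1, pbldp, mchr1b and st6gal2a, the 3 mutant genotypes had changed the same way against wild type, and for slc25a14 and sult1st1 BRAF;p53 did not pass against p53 or against BRAF. For mchr1b and st6gal2a BRAF was above wild type and BRAF;p53 below p53, both past the threshold. Members of the lists fixed in advance with an interaction were cryaa (1.92), cnmd (1.14), vtnb (0.99), gnb1b (0.82), hapln1a (0.79), plk3 (-0.68) and tk1 (-1.11, with 1.17 on its other probe set). For the lists, camera gave adjusted p = 4.8e-05 for exocrine pancreas and 0.0295 for intestine, both lost with an estimated correlation.

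An interaction can arise where 1 genotype stands apart. Wild type was the genotype farthest from the mean of the others in 0.193 of the 497 probe sets, beside 0.179 of all probe sets, which argues against wild type standing apart as the source of most of the 497, though it was the farthest in those 5 of the 10. BRAF was farthest in 0.489, above the bound of 0.4 set beforehand, but it was also farthest in 0.396 of all probe sets, so BRAF embryos standing apart may account for many of the interactions while the test separates little. Leaving out BRAF replicate 1, the array with the widest values, raised the count to 664, of which 435 were among the 497. Counts rose in the same fit where that genotype was not compared, from 284 to 466 for p53 against wild type, so the rise does not bear on the source. Most of the 497 stayed called without that array and so did not hang on it. A biological dependence of the BRAF effect on p53 stays open, as do clutch or handling differences of the BRAF samples, for which the labels give no batch.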

How the results depend on the processing

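Alternatives added after seeing the data were the fit without the 2 arrays farthest from their genotype, the mean of the probe sets of each gene, and the fit without probe sets of median below 1. Counts are given in the order BRAF;p53, BRAF and p53 against wild type, BRAF;p53 against p53, BRAF;p53 against BRAF, and interaction. The reported counts were 302, 993, 284, 456, 698 and 497. They were 165, 574, 140, 257, 401 and 295 with 1 probe set per gene, and 171, 595, 146, 264, 434 and 312 with the mean per gene, where fewer features were tested. A log2 change of at least 1 left 145, 350, 121, 171, 220 and 317. Quantile normalization gave 774 for BRAF;p53 against wild type and 697 for BRAF;p53 against p53. Averaging p53 samples 1a and 1b gave 156 for p53 against wild type, 254 for BRAF;p53 against p53 and 312 for the interaction, with fewer arrays. With only the genotypes compared fitted, the comparisons against wild type gave 836, 598 and 105. The spread between arrays was unequal: the SD of log2 differences between replicates was 0.207 to 0.245 in BRAF;p53, 0.244 to 0.53 in BRAF and 0.27 to 0.445 in p53. The fit of all arrays gives every genotype the same spread. Its counts are therefore not a like measure of how far genotypes differ, and its p-values may be too small or too large. Without the 2 farthest arrays the counts were 916, 1766, 688, 1227, 1162 and 1469. The p53 group then held only samples 1a and 1b, which may not be independent. Where no construction is named, the cause was not tested. Leaving out 1 array gave 162 to 510, 595 to 1188, 161 to 466, 179 to 688, 302 to 982 and 284 to 787. Centred medians, trend and robust settings and the omission of median-below-1 probe sets stayed within 1.5 times. Centring moved the share of higher calls by at most the step from 49.7% to 43.1%.

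The number of lists past camera was 0, 1, 0, 2, 4 and 2. With an estimated correlation it was 0 in all 6, and with fry 0 for BRAF;p53 against p53 and 2 for BRAF;p53 against BRAF. It was 2, 3, 3, 2, 9 and 7 without the 2 farthest arrays. In BRAF against wild type it was 0 without median-below-1 probe sets, and in p53 against wild type it was 1 there and 1 with the mean per gene. Leaving out 1 array gave 0 to 3, 0 to 3, 0 to 2, 1 to 3, 1 to 10 and 1 to 4. The cause was not tested.

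Replicate numbers did not clearly pair the samples: of 18 same-numbered pairs 7 had deviations correlated above 0.1 (range -0.32 to 0.36), and 6 of 12 arrays correlated best with their own number. The median correlation was 0.065 for same-numbered pairs and -0.055 for other pairs, so a partial pairing is not excluded. With a replicate block the counts were 328, 996, 316, 424, 703 and 481 and the lists 0, 0, 0, 3, 5 and 2.

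Of 149 named calls 144 kept under quantile normalization, 143 with centred medians, 141 with the block, 131 with 1a and 1b averaged, 140 with trend and robust settings, 146 without the 2 farthest arrays, and 119 to 148 with 1 array left out, lowest without BRAF;p53 replicate 1. With only the genotypes compared 110 of 132 pairwise calls kept, and with the mean per gene 132 of 149 kept, 14 were lost and 3 reversed. The 3 were of tk1: the mean of its probe sets gave -0.04, 0 and 0.03 for BRAF against wild type, BRAF;p53 against BRAF and the interaction, since its 2 probe sets move oppositely. The correlation of BRAF effects stayed at 0.074 to 0.194 with 1 array left out. That of p53 effects ranged from -0.066 to 0.18 and was -0.167 without the 2 farthest arrays. Absolute level is not in the table, so the planned filters on dim probe sets and the pseudocount were not run, and what signal over background limits is unknown.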

Other observations

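Of the tests in this part, those relating the pancreas list to other lists were chosen after the pancreas values had been seen, the interaction count and the fits without wild-type arrays for the 64 probe sets were added after the results, and the lens list was picked out for description after all 22 lists had been tested. The lens gene cryaa differed between genotypes, and the list mean moved with it: the mean of the 6 measured genes of the lens list was -0.55, -0.56 and -0.63 on the BRAF arrays and between -0.43 and -0.24 on the other 9. Among 22 lists it was the only one whose genotype means spread more than in other groupings of the arrays (exact permutation p = 0.000455 over 15400 groupings, Benjamini-Hochberg p = 0.01). The difference rests on cryaa, at -1.61 against wild type the only 1 of the 6 to pass in BRAF embryos. The median difference of the 6 genes was -0.055 and camera did not pass (adjusted p = 0.455), so no change of lens genes in general is shown.

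The exocrine pancreas list varied widely between arrays of 1 genotype. The largest range within a genotype was 27 times that of the array medians, which argues against a shift of whole arrays remaining in the deposited values. Distortions that leave the array median in place were not tested. The effect of genotype on the list mean stays open (exact permutation p = 0.269). After genotype means were removed, pancreas and intestine means moved together over the 12 arrays (r = 0.95, rho = 0.93, exact permutation p = 0.000772, the smallest that 1296 rearrangements within genotypes can give; r = 0.95 without the 2 arrays farthest from the median). Of 21 lists related to the pancreas list, 4 passed Benjamini-Hochberg: intestine (p = 0.0162), circadian genes (r = 0.93, p = 0.0162), photoreceptors (r = 0.95, p = 0.0324) and purine and pyrimidine synthesis (r = -0.67, p = 0.0486). Differences in developmental progress or digestive state of the embryos may underlie this, as a hypothesis from these data. Array-to-array shifts of this kind accompany the pancreas and intestine differences between genotypes.

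In 64 probe sets the 3 mutant genotypes differed from wild type the same way. In 100 simulations of unchanged groups 0 did so on average, so shared error alone gave none where no probe set was changed. Such groups hold almost no calls, so this cannot show how shared wild-type error adds to overlap among many calls. Of the 64, 42, 42 and 43 stayed called without wild_type replicate 1, 2 and 3, 33 of them in each of these fits. These fits still share the remaining wild-type arrays. Covariances of fold changes, 0.0658, 0.0558 and 0.045, exceeded the simulated 0.02, while correlations of 0.46, 0.5 and 0.33 did not exceed the simulated 0.5, so some contribution of the shared arrays is not excluded. Whether effects of BRAF and p53 add was also asked. The change in BRAF;p53 was 0.517 of the sum (median, 95% bootstrap interval 0.501 to 0.539 over probe sets, which share arrays, bound 0.75). The set was picked from these data by 3 differences that share wild type. A deviation of wild type alone gives 0.5 of the sum, so this ratio cannot decide for the set. The interaction, whose error includes the wild-type arrays, passed against adding in 39 of the 64 and left 25 undecided. A deviation of wild type alone also gives an interaction against the sum, so these counts cannot decide for the set either. A difference in the probes' target sequence between the lines and wild type stays open. In 33 pairings of 1 of the 64 with another probe set of its gene, a share of 0.333 moved the same way by at least 0.5 of the change. The share was 0.31 with only probe sets of another target and 0.33 for genes changed in 1 or 2 genotypes. The share of 0.333 lay between the bounds set beforehand. Some pairings, for slc25a14, ndst2a and mkrn4, joined 2 of the 64, which were picked for moving the same way. Such pairings raise the share, so it cannot decide. A difference in genetic background between the wild-type strain and the mutant lines is a candidate explanation that was not tested.

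For each pairwise comparison, 3 arrays against 3 allow 10 splits and no share under 0.1. In every comparison 1 of the 10 splits, the real one, gave as many probe sets with only those 6 arrays fitted, and the highest other split gave 0, which leaves an arbitrary grouping undecided at this resolution. The real counts were 836 for BRAF;p53, 598 for BRAF and 105 for p53 against wild type, 367 for BRAF;p53 against p53 and 596 for BRAF;p53 against BRAF.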
